A study of Mus musculus with 15 samples.

How the data were processed

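Ventral prostate RNA of 15 TRAMP samples was extracted with TRIzol and RiboPure, labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited table holds log2 expression values that the authors made with RMA (robust multi-array average), whose version was not given in the sources used here. It has 34760 probe sets and values from 1.10 to 13.11 on the log2 scale. No array was identical to another, and all 15 columns belonged to the 15 samples. The arrays were not background-corrected or normalised again, so the values used were those of the authors.

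Probe sets were given gene symbols from the array annotation of 2016, updated by gene identifier to the mouse reference annotation where the identifier was found (21553 of 21640 probe sets with 1 symbol). The annotation listed 22961 probe sets. The 1321 with several symbols and the 11799 not listed were left out of the gene tests and examined apart. Where a gene had several probe sets (954 genes), the one with the highest mean over all arrays was used, which left 19937 genes. Positions are gene bounds on chromosomes of the GRCm38 annotation, not those of the probe sets.

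Groups followed the labels on treatment and time. A linear model with 4 group means was fitted over all 15 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and no intensity trend (11 residual and 4.93 prior degrees of freedom). The 6 comparisons were calcitriol against control at 12 h, at 24 h and on average over both, the difference of the effect between 24 h and 12 h, and 24 h against 12 h in controls and in calcitriol samples. Two-sided p values were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. The labels do not say whether each sample came from a separate animal, so p values measure the spread between these samples. The comparisons of calcitriol with control share no samples between 12 h and 24 h.

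The comparisons, the tests, the alternatives, the rule for named genes and 36 gene lists (20 pathways and responses, 16 cell or tissue types) were choices made before the data were examined. Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 35 tested lists of a comparison, and again with an estimated correlation, with fry and with exact permutation of the list means. Each list's genes were also adjusted over the list alone. That adjustment does not cover the number of lists and comparisons, so some genes can pass it by chance. Several genes stood in more than 1 list, such as 2 shared by androgen response and secretory proteins and 2 by androgen response and glucocorticoid response. Many cell type markers are also expressed by other cells of the prostate.

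Named genes were the 10 higher and 10 lower with the largest fold among those past the threshold at 12 h, at 24 h and on average, and 5 and 5 in the other comparisons. Where fewer than 5 passed in a direction, genes were added up to 5 by the smallest unadjusted p and said not to have passed. Unnamed and predicted genes, microRNA and olfactory or vomeronasal receptor genes were counted but not named. By the rule Vdr, Cyp27b1, Fkbp5, Pbsn, Tmprss2 and Mki67 were fixed genes to report, with up to 4 members of each described list. The text departs from it, since more members of some lists are named and the fixed genes are not given in every comparison.

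The alternatives were an intensity trend with a robust prior, quantile normalisation between arrays, centring each array on its median, leaving out the 25% or 50% of genes with the lowest mean, the mean of a gene's probe sets, array weights, the sample number as a block, an ordinary model without moderation, a fit on the groups of a comparison alone and leaving out each sample in turn. The exact test of a list mean within 1 time or 1 treatment cannot give a p below 0.0286. Adjusted over the 35 lists it can pass only if most lists reach that p. The test was checked on simulated data with 200 changed genes. At a log2 change of 0.4, 66% of 50 genes were recovered in the 12 h comparison and 88% in the 24 h comparison, and at 0.7 these were 98% and 96%. False calls numbered 11 of 193 and 10 of 202. The recovered shares hold for 200 changed genes with changes of up to 1.5. Where fewer genes change, the adjusted threshold is harder to pass. The shares therefore do not show which sizes of change were missed in comparisons with 0 calls. A list shifted by -0.30 was recovered and none of the other lists was called. The simulated genes varied independently of each other. The check therefore could not reveal false calls of genes or lists that arise from correlation between genes. For splits of the samples, the 35 splits within a time or treatment were all run, and 100 were drawn where there were more.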

Results

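Gene expression was measured in the ventral prostate of TRAMP mice, a transgenic strain in which a viral oncogene driven by the probasin promoter causes prostate cancer. The mice came from a cross of TRAMP with FVB and were 10 weeks old. They received calcitriol, the hormonal form of vitamin D, at 20 µg/kg by intraperitoneal injection on a Monday, Wednesday and Friday schedule, or a control treatment. Prostates were taken 12 h or 24 h after treatment, and total RNA was read on an Affymetrix array. The 15 samples formed 4 groups, with 3 controls at 12 h, 4 calcitriol samples at 12 h, 4 controls at 24 h and 4 calcitriol samples at 24 h. The array medians lay between 6.44 and 6.52 on the log2 scale, and the correlation between any 2 arrays lay between 0.981 and 0.994. The number of arrays limits the precision of every value. Errors after ± are standard errors of the fitted log2 fold change unless SD is named. Cyp24a1, Ar and Nkx3-1, which belonged to the fixed gene lists, were not analysed here.

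The first comparison asked how calcitriol changed expression at 12 h, with 4 calcitriol samples against 3 controls. Several genes that the vitamin D receptor is known to drive in calcium and metal handling were higher. S100g, an intracellular calcium-binding protein, went from 5.74 ± 0.13 (SD, n = 3) to 6.86 ± 0.55 (SD, n = 4), a log2 fold change of 1.11 ± 0.21. The manganese exporter Slc30a10 differed by 0.58 ± 0.14 and the calcium pump Atp2b1 by 0.18 ± 0.06. All 4 calcitriol samples lay above every control for S100g and for Slc30a10. Of the 18 measured vitamin D receptor targets, S100g (adjusted p = 0.00135), Slc30a10 (0.00564) and Atp2b1 (0.0431) rose and 0 fell at 12 h when adjusted over the list alone. Vdr, the receptor itself, differed by -0.23 ± 0.08 with all 4 calcitriol samples below every control, and missed that threshold (adjusted p = 0.0658 over the list alone). The camera test of the list as a whole gave an adjusted p of 0.516, with 9 members higher and 9 lower and a mean shift of 0.08 against a median of -0.004. The fry test for change in either direction gave an adjusted p of 7.39e-05. In the list of other calcium and vitamin D metabolism genes, Cyp27b1, the enzyme that makes calcitriol, rose by 0.19 ± 0.05 when adjusted over the list alone (adjusted p = 0.0229), while the list gave a camera adjusted p of 0.758. Over all genes Cyp27b1 did not pass in limma (adjusted p = 0.49), and its mean levels were 5.72 in controls and 5.91 with calcitriol. S100g (probe set 10607705) lies on chromosome X from 162961992 to 162964599 and Vdr (probe set 10432032) on chromosome 15 from 97854427 to 97908296 in the GRCm38 annotation.

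**Figure D1:**
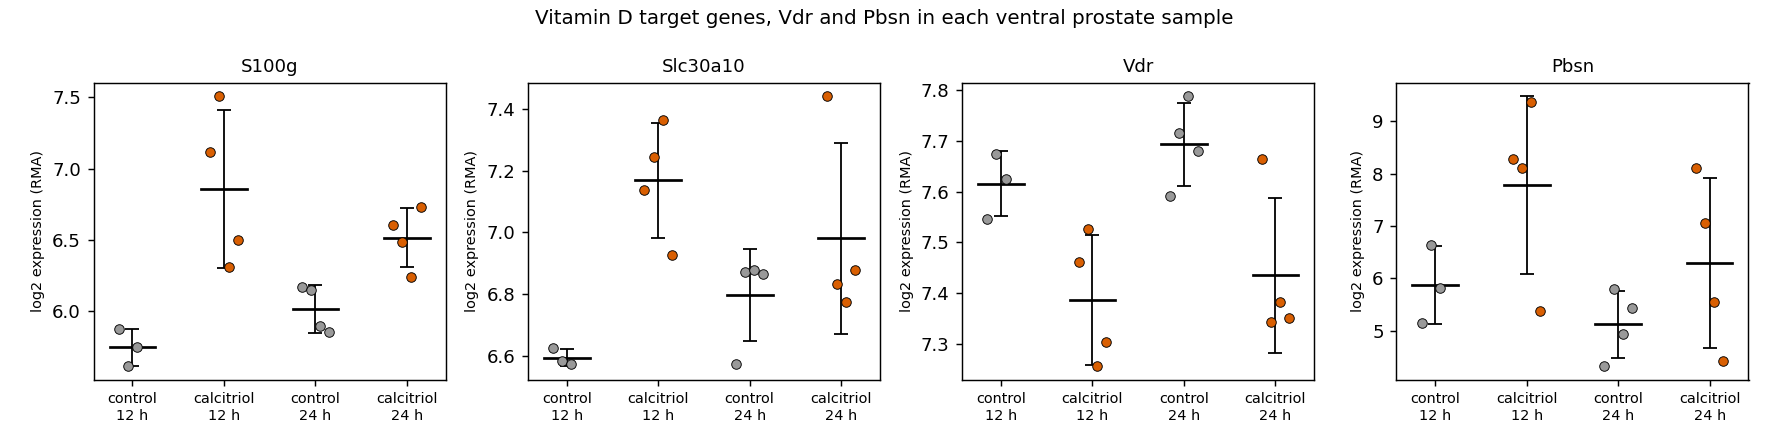
Expression (log2, y axis) of S100g, Slc30a10, Vdr and Pbsn in each of the 15 samples by group (x axis), with points for samples (grey control, orange calcitriol), lines for group means and bars for SD. S100g in the calcitriol samples at 12 h lay between 6.31 and 7.51, above all 3 controls (5.61 to 5.88), and Pbsn in those samples ranged from 5.37 to 9.36.

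The genes with the smallest p at 12 h did not pass the threshold over all genes, each with an adjusted p of 0.0973. On the higher side these were Krt7, a keratin of simple epithelia (0.56 ± 0.10), the phosphatase inhibitor Ppp1r1b (0.38 ± 0.06), Cstdc1 (0.36 ± 0.07), the transcription factor Junb (0.35 ± 0.06) and Arhgef38 (0.32 ± 0.06). On the lower side they were the cell cycle kinase Cdk6 (-0.51 ± 0.09), Cdkl3 (-0.41 ± 0.07), the glutamate receptor subunit Gria1 (-0.35 ± 0.06), the Wnt pathway transcription factor Tcf7l1 (-0.33 ± 0.06) and Dpy19l3 (-0.30 ± 0.05). All 4 calcitriol samples lay beyond every control for Cdk6, Junb and Ppp1r1b. Over all 19937 genes limma called 0 genes at 12 h, and an ordinary linear model without moderation also called 0. An unadjusted p under 0.05 was found for 1212 genes, 500 higher and 712 lower, where 997 would be expected by chance. The count went to 10 with an intensity trend and robust prior and to 257 with array weights.

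Interferon response genes were lower in calcitriol samples at 12 h, all 19 measured members with a mean shift of -0.25. The list mean went from 7.78 ± 0.11 (SD, n = 3) to 7.53 ± 0.21 (SD, n = 4), with 3 of the 4 calcitriol samples below every control. The chemokines Cxcl9 (-0.54) and Cxcl10 (-0.37 ± 0.14), the guanylate-binding protein Gbp3 (-0.37) and the antiviral gene Ifit2 (-0.17) were among them, and 0 of the 19 passed in limma when adjusted over the list alone. The list shifted down in camera (adjusted p = 3.9e-08), with adjusted p = 0.789 with an estimated correlation. Genes of MHC and antigen presentation shifted down by -0.22 on average, with 8 of 10 lower, among them Cd74 (-0.50), H2-Ab1 (-0.50), Tap1 (-0.24) and Psmb8 (-0.13). Their camera adjusted p was 0.00426, with adjusted p = 0.822 with an estimated correlation. The mean of the MHC list ranged from 8.28 to 8.81 in controls and from 8.22 to 8.36 with calcitriol, so the size of the shift depended on single controls. Among cell markers measured beside these lists, T cell genes shifted by -0.10, with Cd3e at -0.20 and Cd8a at -0.24 (camera adjusted p = 0.0315, adjusted p = 0.789 with an estimated correlation). Macrophage genes shifted by -0.07 (0.182) and B and plasma cell genes by 0.09 (0.241), and neither list passed. Without control 12 h sample 2 the calls of the MHC list (adjusted p = 0.593) and the T cell list (0.218) ended, and the T cell call also ended without control 12 h sample 3 (0.133) or calcitriol 12 h sample 2 (0.0643).

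Secretory proteins of the ventral prostate shifted up at 12 h, with 8 of 10 members higher and a mean shift of 0.30 against a median of 0.18 (camera adjusted p = 0.0256, adjusted p = 0.537 with an estimated correlation). Their largest difference was in Pbsn, probasin, an androgen-driven secreted protein, at 1.91 ± 0.83 (limma adjusted p = 0.812). Its level was 5.87 ± 0.74 (SD, n = 3) in controls and 7.77 ± 1.70 (SD, n = 4) with calcitriol, with 3 of the 4 calcitriol samples above every control. The transglutaminase Tgm4 (0.17) and the kallikrein Klk1b27 (0.23) differed less. On this list mean calcitriol 12 h sample 4 stood at 8.59, against 8.97 to 9.02 in the other 3. The unfolded protein and integrated stress response list shifted up by 0.07, with 17 of 20 members higher, such as Manf (0.23), at a camera adjusted p of 0.023 (adjusted p = 0.822 with an estimated correlation). Smooth muscle genes shifted down by -0.11, with Myl9 at -0.26, Myh11 at -0.25 and Acta2 at -0.15 (0.00426, adjusted p = 0.822 with an estimated correlation). Urothelium genes shifted up by 0.13, with Upk1b at 0.23 (0.0371, adjusted p = 0.822 with an estimated correlation). Each of these 4 calls ended without single samples, with adjusted p up to 0.207 for the secretory list (control 12 h sample 3), 0.434 for the stress response (calcitriol 12 h sample 3), 0.527 for smooth muscle (control 12 h sample 2) and 0.148 for urothelium (calcitriol 12 h sample 1).

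The labels name androgen receptor signalling, and its gene lists did not pass at 12 h. Of 31 measured androgen response genes 11 were higher and 20 lower, and camera placed the list down (adjusted p = 0.338) although its mean shift was 0.03 and its median -0.02. Fkbp5, a steroid receptor chaperone, differed by -0.06 ± 0.11 and the protease Tmprss2 by -0.004 ± 0.08. Of the measured androgen receptor partners 2 were higher and 7 lower, with camera placing the list down (adjusted p = 0.203) at a mean of 0.002 and a median of -0.05. Of the fatty acid synthesis list, the transcription factor Mlxipl rose by 0.20 ± 0.06 when adjusted over the list alone (adjusted p = 0.0485). Of the immediate early genes, Junb rose when adjusted over the list alone (0.000517), and the list gave a camera adjusted p of 0.439.

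The second comparison asked how calcitriol changed expression at 24 h, with 4 calcitriol samples against 4 controls. Mitosis genes fell, all 29 measured members, when adjusted over the list alone. Plk1, the kinase that drives mitotic entry, differed by -0.61 ± 0.11, the kinesin Kif23 by -0.66 ± 0.12, the cyclin Ccna2 by -0.57 ± 0.12 and the anaphase activator Cdc20 by -0.45 ± 0.09. The list mean went from 7.86 ± 0.11 (SD, n = 4) in controls to 7.44 ± 0.15 (SD, n = 4) with calcitriol, a shift of -0.42 with a median of -0.40. All 4 calcitriol samples lay below every control. The camera adjusted p was 5.18e-47, with adjusted p = 0.16 with an estimated correlation, and the fry test for a shift in 1 direction gave an adjusted p of 0.0645. An exact two-sided permutation test of the list mean gave p = 0.0286, the smallest that 4 samples against 4 allow, and 0.667 after adjustment over the 35 lists. The adjusted value could pass only if most of the 35 lists reached that smallest p. Plk1 (probe set 10557156) lies on chromosome 7 from 122159435 to 122169884, and the proliferation marker Mki67 differed by -0.35 ± 0.10 (limma adjusted p = 0.338).

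**Figure D2:**
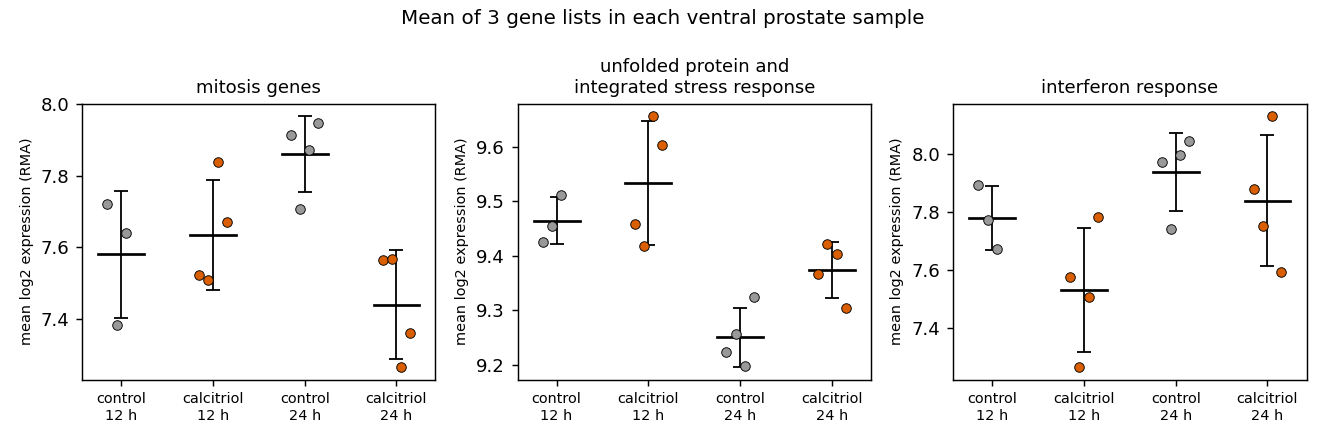
Mean log2 expression (y axis) of the mitosis, unfolded protein and integrated stress response, and interferon response lists in each of the 15 samples by group (x axis), with points for samples (grey control, orange calcitriol), lines for group means and bars for SD. The mitosis mean of the calcitriol samples at 24 h lay between 7.27 and 7.57, below the controls at 24 h (7.71 to 7.95).

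Among single genes at 24 h, those with the smallest p on the lower side did not pass the threshold over all genes. They were the cytoskeletal linker Gas2l3 (-0.52 ± 0.07, adjusted p = 0.0638), the linker histone H1f10 (-0.41 ± 0.06, 0.0672), the mitotic kinesin Kif18b (-0.55 ± 0.09, 0.0672), the core histone H2ac4 (-0.72 ± 0.12, 0.0778) and Plk1 (0.0943). The higher side held Hyou1, an endoplasmic reticulum chaperone (0.40 ± 0.07, 0.0672), Creld2 (0.66 ± 0.11, 0.0778), the membrane fusion protein Snap23 (0.29 ± 0.05, 0.0778), Caln1 (0.61 ± 0.11, 0.103) and Fam160a1 (0.36 ± 0.07, 0.103). All 4 calcitriol samples lay beyond every control for Gas2l3, H1f10, Kif18b, H2ac4, Plk1, Hyou1, Creld2 and Snap23. Over all genes limma called 0 genes at 24 h, and the model without moderation also called 0. An unadjusted p under 0.05 was found for 1170 genes, 527 higher and 643 lower, against 997 expected. The count went to 17 with an intensity trend and robust prior and to 9 with array weights.

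Genes of protein folding stress, cholesterol synthesis and the immediate early response shifted up at 24 h. In the unfolded protein and integrated stress response list 17 of 20 members were higher, with a mean shift of 0.12, and Hyou1, Creld2, Hspa5 (0.38 ± 0.08) and Manf (0.23 ± 0.07) rose when adjusted over the list alone. The camera adjusted p was 8.59e-07, with adjusted p = 0.404 with an estimated correlation. In cholesterol synthesis 15 of 17 members were higher, with a mean shift of 0.15, and the sterol sensor Insig1 (0.61 ± 0.13) and the synthase Hmgcs1 (0.22 ± 0.07) rose when adjusted over the list alone (camera adjusted p = 2.76e-06, adjusted p = 0.404 with an estimated correlation). Of the 22 immediate early genes 16 were higher, with a mean shift of 0.12. The transcription factors Atf3 (0.51 ± 0.13), Egr1 (0.48 ± 0.15) and Egr2 (0.34 ± 0.10), with Ccn1 (0.38) and Btg2 (0.21), rose when adjusted over the list alone (camera adjusted p = 2.48e-05, adjusted p = 0.404 with an estimated correlation). In calcitriol 24 h sample 3 Egr1 stood at 7.96, against 8.55 to 8.67 in the other 3.

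Glucocorticoid response genes shifted down at 24 h by -0.10 on average, with 11 of 15 lower. The metallothioneins Mt2 (-0.38 ± 0.09) and Mt1 (-0.33 ± 0.09), the lipase inhibitor Angptl4 (-0.31 ± 0.08), the kinases Pdk4 (-0.35 ± 0.11) and Sgk1 (-0.25), and Klf9 (-0.13) fell when adjusted over the list alone, while Tsc22d3 rose by 0.27 ± 0.09. The camera adjusted p was 0.00312, with adjusted p = 0.404 with an estimated correlation, and control 24 h sample 1 stood at 8.18 on this list mean, against 8.37 to 8.39 in the other 3. DNA replication genes shifted down by -0.10, with 22 of 27 lower, such as the polymerase Pole (-0.25) and the cyclin Ccne1 (-0.24), and 0 passed in limma when adjusted over the list alone (camera adjusted p = 2.48e-05, adjusted p = 0.736 with an estimated correlation). Interferon response genes shifted by -0.10, with 13 of 19 lower, and Ifit2 fell by 0.24 when adjusted over the list alone (camera adjusted p = 0.0385, adjusted p = 0.736 with an estimated correlation). Secretory proteins shifted by 0.21 on average against a median of 0.06, with Pbsn at 1.16 ± 0.77 and every other member at 0.31 or less (camera adjusted p = 0.0287, adjusted p = 0.384 with an estimated correlation). Oxidative phosphorylation genes shifted by 0.04 and neuroendocrine cell markers by -0.15, each with a camera adjusted p of 0.0287 and adjusted p = 0.736 with an estimated correlation. Without control 24 h sample 1 the neuroendocrine shift turned up (adjusted p = 0.951), and the calls of the secretory (0.0668), oxidative phosphorylation (0.198) and interferon (0.116) lists ended.

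The vitamin D and androgen lists did not pass in camera at 24 h. Vitamin D receptor targets had 12 of 18 members higher and a mean shift of 0.05 (camera adjusted p = 0.369). S100g differed by 0.50 ± 0.20 with all 4 calcitriol samples above every control, Vdr by -0.26 ± 0.08 and Cyp27b1 by 0.05 ± 0.05, and 0 targets passed in limma when adjusted over the list alone. Androgen response genes had 21 of 31 higher and a mean shift of 0.06 (camera adjusted p = 0.275), with Fkbp5 at 0.02 ± 0.11 and Tmprss2 at -0.03 ± 0.07. Of the androgen receptor partners, the cochaperone Fkbp4 rose by 0.21 ± 0.05 when adjusted over the list alone (adjusted p = 0.00765), and the list gave a camera adjusted p of 0.302.

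The third comparison averaged the calcitriol effect over both times, with 8 calcitriol samples against 7 controls. Cdk6, a kinase that moves cells from the first gap phase towards DNA synthesis, fell by 0.44 ± 0.06, a 1.36-fold decrease (limma adjusted p = 0.0275). Its levels were 8.40 ± 0.15 (SD, n = 3) and 7.90 ± 0.15 (SD, n = 4) at 12 h and 8.32 ± 0.12 (SD, n = 4) and 7.95 ± 0.06 (SD, n = 4) at 24 h, control first. All 8 calcitriol samples lay below every control of their time. Cdk6 (probe set 10519324) lies on chromosome 5 from 3341004 to 3531008. It was the only gene of 19937 past the threshold, and 1167 genes had an unadjusted p under 0.05. The call ended in 9 of the 15 fits that left out 1 sample (adjusted p from 0.0197 to 0.125 over the 15) and without moderation of the variances (0.102). The count of genes was 0 with the sample number as a block and 0 without the 2 arrays farthest apart on the first principal component, 6 with median centring, 11 with an intensity trend and robust prior, 11 without the 25% or 50% of genes with the lowest mean and 80 with array weights.

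The next genes by p on average did not pass, each with an adjusted p of 0.0829. They were S100g (0.81 ± 0.14), the fucosyltransferase Fut2 (0.33 ± 0.05), Sytl3 (0.29 ± 0.05), Ppp1r1b (0.25 ± 0.04) and Junb (0.23 ± 0.04) on the higher side, and the transcription factors Tox3 (-0.33 ± 0.06), Foxp2 (-0.27 ± 0.05) and Tcf7l1 (-0.23 ± 0.04) and the fatty acid dehydrogenase Acadl (-0.22 ± 0.04) on the lower side. Of the vitamin D receptor targets S100g, Slc30a10 and Atp2b1 rose and Vdr fell by 0.24 ± 0.06 when adjusted over the list alone (Vdr adjusted p = 0.00497), and the list gave a camera adjusted p of 0.233. In the other vitamin D list the retinoid receptor Rxrg rose by 0.27 (0.0143 over the list alone). Interferon response genes shifted down, with 18 of 19 lower and Ifit2, Rsad2, Oasl2, Oasl1 and Cxcl10 falling when adjusted over the list alone (camera adjusted p = 1.26e-08, adjusted p = 0.389 with an estimated correlation). Camera called 11 lists on average and 0 with an estimated correlation. Beside those named, they were mitosis (2.18e-20), the stress response (2.58e-08), MHC (0.000256), immediate early genes (0.000256), secretory proteins (0.000384), DNA replication (0.0012), cholesterol synthesis (0.00367), glucocorticoid response (0.0198), T cells (0.0333) and oxidative phosphorylation (0.0333), with adjusted p from 0.0813 upward with an estimated correlation. Androgen response genes split 15 higher to 16 lower, and camera placed the list down (adjusted p = 0.959) at a mean of 0.05 and a median of -0.003.

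The fourth comparison asked whether the calcitriol effect differed between 24 h and 12 h. Mitosis genes differed as a list, with all 29 members more negative at 24 h, by -0.47 on average. Of these, 28 passed when adjusted over the list alone, among them Ccna2 (-0.73 ± 0.18), Plk1 (-0.71 ± 0.16), Kif23 (-0.67 ± 0.18) and Cdc20 (-0.61 ± 0.13). The camera adjusted p was 1.61e-29, with adjusted p = 0.599 with an estimated correlation. At 12 h the list had shifted by 0.05 (camera adjusted p = 0.162), and its means were 7.58 ± 0.18 (SD, n = 3) in controls and 7.64 ± 0.15 (SD, n = 4) with calcitriol. Smooth muscle genes (0.18) and cholesterol synthesis genes (0.16) differed towards a higher effect at 24 h, each with a camera adjusted p of 0.00123 and adjusted p = 0.835 with an estimated correlation. Among single genes limma called 0, the smallest adjusted p was 0.462, and 1256 genes had an unadjusted p under 0.05. Those with the smallest p were Dact1 (0.74 ± 0.15), Gria1 (0.48 ± 0.09), Lzic (0.41 ± 0.09), Mrpl22 (0.40 ± 0.09) and Snap23 (0.37 ± 0.07) towards a higher effect at 24 h, and the histones H2ac4 (-0.85 ± 0.18) and H2bc3 (-0.69 ± 0.15), Cdc20, Gas2l3 (-0.50 ± 0.11) and Cstdc1 (-0.42 ± 0.09) towards a lower one. Without control 12 h sample 2 the smooth muscle call ended (0.109), and without control 12 h sample 1 the cholesterol call ended (0.147).

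The fifth comparison set 24 h against 12 h in controls, 4 samples against 3. Genes of the circadian clock changed. Nr1d1 rose by 1.20 ± 0.17 (adjusted p = 0.00953), Dbp by 1.02 ± 0.11 (0.000436), Per3 by 0.89 ± 0.08 (0.000136) and Nr1d2 by 0.81 ± 0.13 (0.0143), all repressors or output factors of the clock, while the clock activator Arntl fell by 0.66 ± 0.06 (0.000136). The early growth response factor Egr1 rose by 1.19 ± 0.16 (0.00698). The vault RNA Vaultrc5 (-0.84 ± 0.13, 0.0127), Cstf3 (-0.41 ± 0.07, 0.0384) and the endoplasmic reticulum proteins Pdia4 (-0.46 ± 0.08, 0.0319) and Derl3 (-0.43 ± 0.08, 0.0488) fell. For Nr1d1, Dbp, Per3, Arntl and Egr1 all 4 samples at 24 h lay beyond every sample at 12 h. In total 20 genes passed in limma, 9 higher and 11 lower, and 3111 had an unadjusted p under 0.05. The count was 3430 with array weights, 174 without the 50% of genes with the lowest mean, 64 with an intensity trend and robust prior and 3 without the 2 arrays farthest apart on the first principal component. Without control 24 h sample 4 the count was 108, and it was 6 without control 12 h sample 2, 7 without control 12 h sample 1, 10 without control 24 h sample 2 and 13 without calcitriol 24 h sample 2.

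All 13 measured clock genes that are high when Bmal1 targets are active were higher at 24 h in controls, by 0.54 on average, and 11 passed when adjusted over the list alone. All 4 genes of the opposite phase fell when adjusted over the list alone, by -0.39 on average. The camera adjusted p values were 1.74e-16 and 3.71e-07, and each list gave adjusted p = 0.0277 with an estimated correlation. The clock lists in the time comparisons were the only list calls that held with an estimated correlation. Mitosis genes were higher by 0.28, all 29 of them, with 16 passing when adjusted over the list alone (camera adjusted p = 8.9e-11, adjusted p = 0.582 with an estimated correlation). DNA replication genes were lower by -0.15, 24 of 27 (3.47e-08, adjusted p = 0.582 with an estimated correlation), as were stress response genes by -0.21, 16 of 20, of which 10, such as Creld2 and Hyou1, fell when adjusted over the list alone (2.92e-10, adjusted p = 0.266 with an estimated correlation). The 4 controls at 24 h also enter the 24 h calcitriol comparison, where mitosis and stress response genes shifted the opposite way. Immediate early genes shifted up by 0.18 (0.000898) and smooth muscle (-0.15, 0.00157), cholesterol synthesis (-0.13, 0.00173) and oxidative phosphorylation genes (-0.06, 0.00699) down, with adjusted p of 0.582 or more with an estimated correlation. The smooth muscle call ended without control 12 h sample 2 (0.141) and the cholesterol call without control 12 h sample 1 (0.2).

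**Figure D3:**
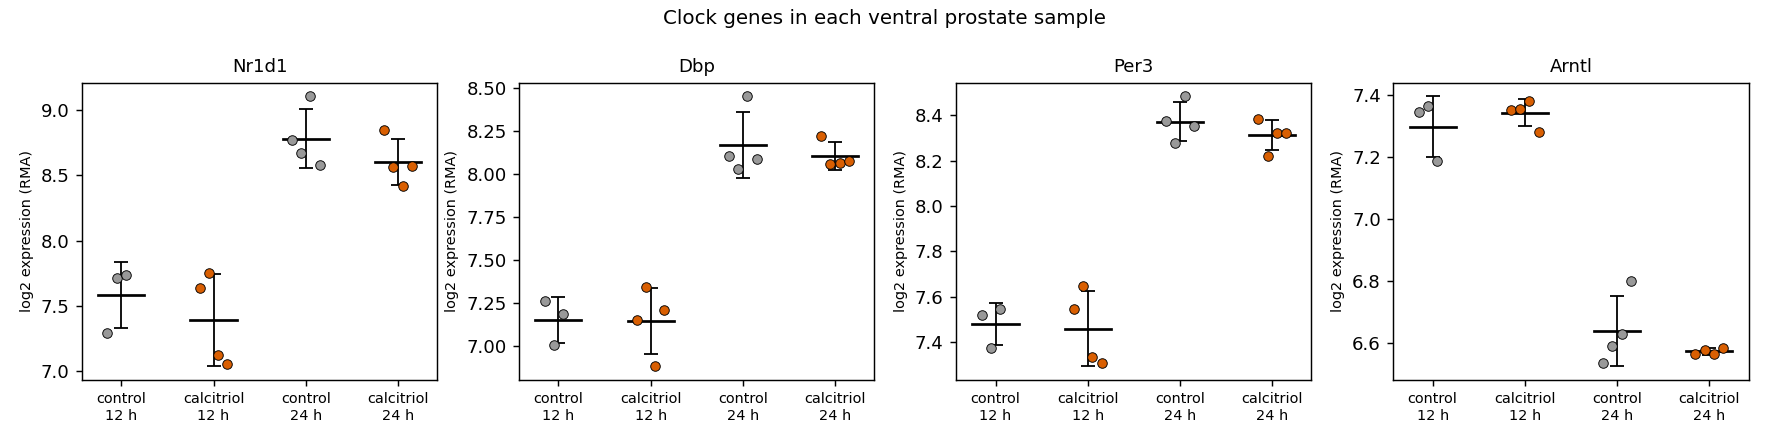
Expression (log2, y axis) of the clock genes Nr1d1, Dbp, Per3 and Arntl in each of the 15 samples by group (x axis), with points for samples (grey control, orange calcitriol), lines for group means and bars for SD. Dbp lay between 6.89 and 7.34 in the 7 samples at 12 h and between 8.03 and 8.45 in the 8 samples at 24 h.

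The sixth comparison set 24 h against 12 h in calcitriol samples, 4 against 4. Clock genes again changed. Nr1d1 rose by 1.21 ± 0.16 (adjusted p = 0.00206), Dbp by 0.96 ± 0.10 (0.000351), Per3 by 0.85 ± 0.08 (4.32e-05) and Nr1d2 by 0.74 ± 0.12 (0.0114), and Arntl fell by 0.77 ± 0.06 (9.61e-06). Egr1 rose by 1.31 ± 0.15 (0.00065). The chaperone Dnajb9 (-0.68 ± 0.12, 0.0195), the replication licensing factor Cdc6 (-0.54 ± 0.10, 0.0434), the glycosyltransferase Mgat2 (-0.49 ± 0.09, 0.0404) and Banp (-0.48 ± 0.07, 0.00767) fell. For Nr1d1, Dbp, Per3, Arntl and Egr1 all 4 samples at 24 h lay beyond every sample at 12 h. In total 37 genes passed in limma, 21 higher and 16 lower, and 1941 had an unadjusted p under 0.05. Without single samples the count fell to 19 (calcitriol 24 h sample 2 or 4), 21 (calcitriol 12 h sample 3) and 23 (calcitriol 12 h sample 2 or 4). The control and calcitriol comparisons shared 10 genes, all 10 in the same direction, among them Nr1d1, Nr1d2, Dbp, Per3, Arntl and Egr1. If genes and comparisons were independent, 0.0371 would be expected by chance. They were not independent, since both comparisons came from 1 fit with a shared variance for each gene. Nr1d1 (probe set 10390691) lies on chromosome 11 from 98767932 to 98775377.

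With calcitriol, clock genes active with Bmal1 targets were higher at 24 h, 13 of 13 by 0.56 on average (camera adjusted p = 4.27e-26, adjusted p = 0.00547 with an estimated correlation), and 11 passed when adjusted over the list alone. Those of the opposite phase fell by 0.43 on average, 4 of 4 (1.69e-10, adjusted p = 0.00592 with an estimated correlation). DNA replication genes were lower, 27 of 27 by -0.24 on average, and 22 of them fell when adjusted over the list alone, such as Cdc6, Rfc4 (-0.34 ± 0.09), Ccne2 (-0.32 ± 0.09) and Mcm4 (-0.28 ± 0.06) (1.21e-24, adjusted p = 0.0765 with an estimated correlation). Mitosis genes shifted by -0.19, 29 of 29, with 0 passing in limma when adjusted over the list alone (2.41e-13, adjusted p = 0.458 with an estimated correlation). Interferon response genes shifted up by 0.31, 19 of 19, and 8 of them, such as Ifit3 (0.78 ± 0.26), Gbp3 (0.43 ± 0.13) and Irf7 (0.45 ± 0.16), rose when adjusted over the list alone (1.08e-08, adjusted p = 0.376 with an estimated correlation). The 4 calcitriol samples at 12 h also enter the 12 h calcitriol comparison. Immediate early genes shifted up by 0.26, with 8 rising when adjusted over the list alone, among them Ccn1 (0.69 ± 0.13), Egr2 (0.61 ± 0.10), Atf3 (0.60 ± 0.13) and Fos (0.39 ± 0.07) (3.84e-11, adjusted p = 0.0674 with an estimated correlation). Stress response genes shifted by -0.16, 18 of 20 (2.92e-10, adjusted p = 0.171 with an estimated correlation). Oxidative phosphorylation genes shifted by -0.04 (0.0403, adjusted p = 0.844 with an estimated correlation), a call that ended without calcitriol 24 h sample 1 (0.165).

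The remaining lists did not pass in camera in any of the 6 comparisons. Of these, vitamin D receptor targets passed at 12 h in the fry test for change in either direction, as given above. Their smallest camera adjusted p over the 6 was 0.051 for neutrophils, 0.0609 for macrophages, 0.0667 for B and plasma cells, 0.0559 for fatty acid synthesis, 0.0704 for androgen receptor partners, 0.0882 for androgen response and 0.0953 for basal epithelium. It was 0.126 for inflammatory cytokines, 0.18 for p53 targets and luminal epithelium, 0.22 for seminal vesicle, 0.233 for vitamin D receptor targets and for oestrogen and progesterone response, 0.239 for adipocytes, 0.27 for fibroblasts and 0.281 for skeletal muscle. It was 0.439 for endothelium, 0.446 for peripheral nerve and 0.695 for other calcium and vitamin D metabolism genes. Median, mean and test also differed in sign for some lists that did not pass, among them seminal vesicle at 12 h (mean 0.03, median 0.08, camera down) and peripheral nerve at 12 h (mean 0.04, median -0.006, camera up). The erythrocyte list had 2 measured members and was not tested. Exact permutation tests of the list means over all 35 lists gave no adjusted p under 0.25 in the comparisons within a time or within a treatment. There an adjusted p could pass only if most lists reached the smallest p, so these tests could not decide about single lists.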

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

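The split counts of genes and lists within each comparison were planned, and the count of genes shared by both time comparisons and all other tests of explanations in this part were chosen after the results were seen.

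Within groups of 4, 18 of 258 tests of gene list means and named genes had 1 sample far from the other 3, where chance gives about 1 in 20, or 13. Among list means, calcitriol 12 h sample 4 stood apart on secretory proteins (8.59, others 8.97 to 9.02), luminal epithelium (10.14, others 10.06 to 10.07) and adipocytes (6.20, others 5.85 to 5.89). Control 24 h sample 1 was low on glucocorticoid response (8.18, others 8.37 to 8.39) and control 24 h sample 4 high on MHC and antigen presentation (8.58, others 8.38 to 8.39). Control 24 h sample 2 was high on vitamin D receptor targets (6.86, others 6.78 to 6.79) and skeletal muscle (6.37, others 6.30 to 6.31), and calcitriol 24 h sample 2 high on fibroblasts (8.25, others 8.02 to 8.04).

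Among named genes, calcitriol 24 h sample 1 was high for Arhgef38 (7.93), Dbp (8.23) and Vdr (7.66), and calcitriol 24 h sample 3 was low for Egr1 (7.96). Calcitriol 12 h sample 1 was low for Cdc20 (7.49) and calcitriol 12 h sample 3 low for Cdkl3 (6.42). Control 24 h sample 3 was low for Pdia4 (10.35) and Snap23 (9.86), control 24 h sample 4 high for Cstf3 (8.22) and control 24 h sample 1 low for Vaultrc5 (6.83).

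The calcitriol effect differed between 24 h and 12 h in a test of the difference for mitosis genes (camera adjusted p = 1.61e-29), cholesterol synthesis (0.00123) and smooth muscle (0.00123). With an estimated correlation these calls ended, at adjusted p = 0.599 for mitosis genes and 0.835 for the other 2 lists, and 93 of 100 splits called as many lists. Of 13120 probe sets outside the gene tests, which have no single gene symbol, probe set 10339363, whose gene is not known here, was the 1 that passed at 12 h (log2 fold change 1.37, adjusted p = 0.000145), the 1 on average (0.57, 0.0494) and the 1 in the difference between times (-1.59, 0.00103), and 0 passed in limma at 24 h, where 704 had an unadjusted p under 0.05. With time, 8 passed in controls, led by the same probe set (1.29), and 15 in calcitriol samples. These counts are adjusted among the 13120, and adjusted over all probe sets of the table they were 1 at 12 h, 0 on average, 1 for the difference between times, 7 with time in controls and 15 in calcitriol samples. The controls at 12 h enter each comparison for which a fold change of probe set 10339363 is given, so these results are not independent.

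Where limma called 0 genes, every split of the samples gives at least as many, so the 35 of 35 splits at 12 h (highest other 0), 35 of 35 at 24 h (highest other 1) and 100 of 100 for the difference between times (highest other 1) test nothing. An unadjusted p under 0.05 was found for 1212, 1170 and 1256 genes in these comparisons, and 7 of 35, 12 of 35 and 18 of 100 splits gave as many (highest other 2174, 2906 and 3023), so chance cannot be excluded for these counts. On average 3 of 100 drawn splits, the real one included, gave as many as the 1 gene called (highest other 18). The share among the other draws has a 95% exact interval that reaches 0.0711, so chance cannot be excluded. For time, 2 of 35 splits gave as many in controls (20 genes, highest other 680) and 2 of 35 in calcitriol samples (37 genes, highest other 100), and chance cannot be excluded for either count alone. An unadjusted p under 0.05 was found for 3111 genes in controls, and 4 of 35 splits gave as many (highest other 5538). In calcitriol samples 1941 genes had one, and 1 of 35 splits, the real one, gave as many (highest other 1885). For the genes called in both arms in the same direction, 1 of 100 relabellings of the times gave as many as the 10 seen (highest other 0). That one was the real labelling, which was included by design. The share among the other draws has a 95% exact interval that reaches 0.0366. This argues against chance, but the count was picked after it was seen, so chance is not excluded. The split of the controls with 680 genes set control 12 h sample 3 with control 24 h samples 1, 2 and 3 against the rest. It thus exchanged control 24 h sample 4 for a 12 h control, and it points to a structure among the samples beside their time. On the first principal component its sides lay at 3.69 to 15.23 and at -18.73 to -5.16. Their array medians over genes were 6.719 to 6.738 and 6.668 to 6.707. The cause of this structure was not tested. The split with 100 genes set calcitriol 12 h sample 4 with calcitriol 24 h samples 2, 3 and 4.

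For the lists called by camera, as many came from 17 of 35 splits at 12 h (7 lists, highest other 12), 4 of 35 at 24 h (10, highest other 13), 8 of 100 on average (11, highest other 12) and 93 of 100 for the difference between times (3, highest other 14). For time they came from 21 of 35 in controls (9, highest other 13) and 15 of 35 in calcitriol samples (8, highest other 13). Chance cannot be excluded for any of these list counts.

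Mitosis genes were lower with calcitriol at 24 h by -0.419, and 1 of 35 splits shifted the list as far, the real one (highest other 0.349). That is the smallest share the design allows, and since the list was picked out of 35 after its result was seen, chance cannot be excluded. The permutation p adjusted over the lists was 0.667. It could pass only if most lists reached the smallest p, so it decides nothing here. Fewer epithelial cells of every kind would lower luminal markers too, and these differed by -0.019 (95% interval -0.065 to 0.027), which argues against it. With median centring or quantile normalisation, whichever was smaller, the shift was -0.408. The array medians already lay between 6.444 and 6.515, so these settings could move a list mean only a little. Their result shows no more than that the arrays differed too little in level to make the shift. It stays open whether the controls at 24 h stood high, since the calcitriol samples at 24 h differed from the controls at 12 h by -0.14 (95% interval -0.386 to 0.105), and an effect of calcitriol on cell division was not tested apart from this.

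Interferon response genes were lower with calcitriol at 12 h by -0.246, but 5 of 35 splits shifted the list as far (highest other 0.331), so chance cannot be excluded. Fewer immune cells could lower such genes, and T cell genes differed by -0.104 (95% interval -0.195 to -0.014) and macrophage genes by -0.068 (-0.29 to 0.155). B and plasma cell genes differed by 0.09 (-0.122 to 0.302), and intervals this wide leave a loss of immune cells open. An effect of calcitriol on interferon signalling stays open as well and was not tested apart from it.

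Pbsn was higher in part of the calcitriol samples, and 107 of 2450 relabellings within times shifted it as far as the 1.534 seen on average (highest other 2.34), a share of 0.0437 that is not adjusted for the choice of this gene. Over all genes its limma adjusted p on average was 0.659, so chance cannot be excluded. A general rise of androgen response genes is argued against, since the other 29 genes of that list differed by -0.007 (95% interval -0.056 to 0.043). Within groups Pbsn followed the mean of the 9 other secretory genes over 15 arrays (r = 0.643, permutation p = 0.00644, Spearman rho = 0.671, permutation p = 0.00812, and r = 0.617 without the 2 farthest arrays). A source shared by secretory genes that differs between samples may therefore contribute, and an effect of calcitriol stays open.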

How the results depend on the processing

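The alternatives were planned, except the fit without the 2 arrays farthest apart on the first principal component (control 12 h sample 2 and control 24 h sample 1), which was chosen after seeing the data (as was the fit of neuron-type genes without control 24 h sample 1 given with them). Direction was kept under all alternatives by 264 of 270 named-gene fold changes and by 47 of 48 called list results. The list of clock genes active with Bmal1 targets kept its call in both time comparisons under the alternative settings, fry and an estimated correlation, with adjusted p up to 0.0277 in controls and 0.00547 in calcitriol samples. In exact permutation of its mean it had the smallest p the design allows (0.0286) and did not pass after adjustment over the lists (0.25). The adjusted p could pass only if most lists reached that smallest p. The groups-alone fit gave no value for the average and the difference between times, since all 4 groups enter them. The cause of the changes was not tested, except that fewer genes or samples entered where some were left out. Signal over background could not be read from the deposited values, so its limit on dim genes is unknown.

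With an intensity trend and robust prior limma called 10 genes at 12 h, 17 at 24 h, 11 on average, 64 with time in controls and 89 with time in calcitriol samples. Quantile normalisation gave 1 gene at 24 h, 33 with time in controls and 4 lists at 12 h. Median centring gave 1 gene at 24 h and 6 on average. Without the 25% of genes with the lowest mean the counts were 10 at 12 h, 6 at 24 h, 11 on average, 36 and 57 with time in controls and calcitriol samples. Without the lowest 50% they were 8, 17, 11, 174 and 114, with 7 lists for the difference between times. Array weights gave 257 at 12 h, 9 at 24 h, 80 on average, 3430 with time in controls and 328 with time in calcitriol samples. No moderation gave 6 and the groups alone 12 with time in controls. Without the 2 arrays the counts were 0 on average and 3 with time in controls, with 4 lists at 12 h and 6 at 24 h.

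The sample numbers were not treated as pairs in the main fit. Same-number samples correlated between -0.424 and 0.14 after group means were removed. They were best matches in 1 of 7 pairs by description and 2 of 7 by title. So few pairs cannot show whether the numbers pair the samples. With the description number as a block the counts were 0 genes on average, 12 genes with time in controls and 7 lists for the difference between times. With the title number as a block they were 1 gene at 12 h, 0 on average, 1 for the difference between times and 11 with time in controls.

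Leaving out each sample in turn gave 0 to 4 genes at 24 h, with 4 without control 12 h sample 1, 3 without control 12 h sample 2, and 1 without calcitriol 12 h sample 4 or calcitriol 24 h sample 1. On average it gave 0 to 3, with 0 without control 12 h samples 2 or 3, calcitriol 12 h sample 1, control 24 h samples 2, 3 or 4, or calcitriol 24 h samples 1, 2 or 4, and 3 without calcitriol 12 h sample 3. The difference between times gave 0 to 1, with 1 without control 24 h sample 3. Time in controls gave 6 to 108, with 7 without control 12 h sample 1, 6 without control 12 h sample 2, 10 without control 24 h sample 2, 108 without control 24 h sample 4 and 13 without calcitriol 24 h sample 2. Time in calcitriol samples gave 19 to 40, with 23 without calcitriol 12 h samples 2 or 4, 21 without calcitriol 12 h sample 3, and 19 without calcitriol 24 h samples 2 or 4. At 12 h each such fit gave 0.

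Lists called ranged from 4 to 8 at 12 h (4 without control 12 h samples 2 or 3 or calcitriol 12 h sample 2), 6 to 15 at 24 h (6 without control 24 h sample 1), 7 to 14 on average (7 without control 12 h sample 2) and 2 to 7 for the difference between times. With an estimated correlation camera called 0 lists at 12 h, 24 h, on average and for the difference between times, and 2 in each time comparison. Directional fry called 0 in those 4, 3 with time in controls and 4 with time in calcitriol samples, and mixed fry 1 at 12 h, 4 at 24 h, 5 on average and 0 for the difference. The interferon list at 12 h had adjusted p = 0.789 with an estimated correlation, 0.666 with directional fry and 0.471 with mixed fry. The mitosis list at 24 h had 0.16 and 0.0645 in the first 2 of these. The neuroendocrine list at 24 h turned to the opposite direction without the 2 arrays (0.92), and ranged from 0.000928 to 0.951 over single samples left out (0.951 without control 24 h sample 1).

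Single list calls that ended without 1 sample were, at 12 h, MHC (control sample 2 0.593), T cells (control samples 2 and 3 0.218 and 0.133, calcitriol sample 2 0.0643), the secretory list (control sample 1 0.131, control sample 3 0.207, calcitriol sample 2 0.0885), the stress response (control sample 1 0.0737, control sample 3 0.132, calcitriol sample 3 0.434, calcitriol sample 4 0.136), smooth muscle (control sample 2 0.527, calcitriol sample 2 0.0627) and urothelium (control samples 1 and 2 0.14 and 0.122, calcitriol samples 1, 2 and 3 0.148, 0.0627 and 0.0752). At 24 h they were the secretory list (control samples 1 and 3 0.0668 and 0.0658, calcitriol sample 3 0.056), oxidative phosphorylation (control samples 1 and 3 0.198 and 0.184, calcitriol samples 2 and 3 0.187 and 0.0618), interferon (control samples 1, 3 and 4 0.116, 0.184 and 0.314, calcitriol samples 1, 2 and 4 0.115, 0.242 and 0.589) and neuroendocrine markers (calcitriol samples 1 and 3 0.16 and 0.105). On average the calls of T cells and oxidative phosphorylation ended without any of 8 and 9 samples (up to 0.144 and 0.136), DNA replication without control 12 h sample 1 (0.248), MHC without control 12 h sample 2 (0.105), cholesterol synthesis without control 12 h sample 3 (0.402) or calcitriol 24 h sample 3 (0.108), and glucocorticoid response without control 12 h sample 2 (0.105), control 24 h sample 4 (0.0567) or calcitriol 24 h sample 1 (0.0578). For the difference between times cholesterol synthesis ended without control 12 h sample 1 (0.147) and smooth muscle without control 12 h sample 2 (0.109). With time in controls cholesterol synthesis ended without control 12 h sample 1 (0.2) and smooth muscle without control 12 h sample 2 (0.141), and with time in calcitriol samples oxidative phosphorylation ended without any of 5 samples (0.0732 to 0.165).

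Small fold changes of genes that passed no test changed sign. At 12 h these were Fkbp5 (0.0551 with array weights, -0.137 to 0.0263 over single samples left out), Tmprss2 (0.0141 with quantile normalisation, 0.00455 with median centring, 0.00778 with array weights, 0.000201 without the 2 arrays, -0.0799 to 0.064 over single samples) and Mki67 (-0.0933 with array weights, -0.0454 without the 2 arrays, -0.0454 to 0.129 over single samples). At 24 h Fkbp5 gave -0.0483 without the 2 arrays and -0.055 to 0.102 over single samples. On average Fkbp5 gave 0.0323 with array weights and -0.0577 to 0.0249 over single samples, and Tmprss2 -0.0545 to 0.0175.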

Other observations

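The gene families, the neuron-type genes and the tests of both hypotheses in this part were chosen after the data were seen.

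Histone genes were lower with calcitriol at 24 h. Of 35 core and linker histone genes 27 were lower and 8 higher, with a mean shift of -0.169 ± 0.056 (SE), and 17 fell when adjusted over the family alone. The shift was -0.170 with quantile normalisation and -0.158 with median centring. Over the 6 families examined, the camera adjusted p was 3.52e-15, with adjusted p = 0.0549 with an estimated correlation, and an exact permutation test gave p = 0.0286, the smallest it can give. The histones H1f10 and H2ac4 were among the genes with the smallest p at 24 h, and the family was chosen after the data were seen. These p values do not cover that choice. At 12 h the family differed by 0.025, and between 24 h and 12 h in calcitriol samples by -0.161, with 29 of 35 lower. Of 50 cytosolic ribosomal protein genes 44 were higher with calcitriol at 24 h, by 0.071 ± 0.032 (SE) on average, and 0 passed in limma when adjusted over the family alone (camera adjusted p = 1.68e-08, adjusted p = 0.213 with an estimated correlation). Of 23 heat shock protein genes 13 were higher and 10 lower with calcitriol at 24 h, and 5 rose when adjusted over the family alone, with a mean shift of 0.068 ± 0.032 (SE) against a median of 0.019 (camera adjusted p = 0.00461, adjusted p = 0.215 with an estimated correlation). Of 40 proteasome genes 29 were higher at 24 h (camera adjusted p = 0.0127, adjusted p = 0.376 with an estimated correlation). Of 45 Dnaj genes 26 were higher (camera adjusted p = 0.0953, adjusted p = 0.413 with an estimated correlation).

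Control 24 h sample 1 stood apart on 11 genes, most of them neuron-type such as Nnat, Elavl4, Syt1, Scg3 and Nefl, but also Peg10 and Mest. These genes averaged 7.32 there and 5.68 in the next highest sample. They were picked from the genes leading the first principal component, where this sample lay highest, so its standing apart follows from that choice. They differed by -0.537 ± 0.354 (SE) with calcitriol at 24 h, and by -0.077 ± 0.114 (SE) without control 24 h sample 1. On the first principal component, which held 26.5% of the variance, control 12 h sample 2 lay at -18.7 and control 24 h sample 1 at 15.2. The calcitriol effects at 12 h and 24 h did not correlate across genes (r = -0.003), although genes are not independent replicates, and 50 of 100 relabellings gave a correlation as large.

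A candidate explanation for the clock genes that differ between 24 h and 12 h in both arms is that the harvests fell at different phases of the daily cycle. It would lower genes of the opposite phase at 24 h in both arms, and these differed by -0.391 in the arm with the smaller shift (95% interval -0.511 to -0.270) and by -0.429 in the other. Those shifts were known before the hypothesis was put, so they are no independent evidence for it, and the hour of harvest was not tested. A related hypothesis is that the time of harvest acted alike in both arms beyond the clock genes. With the clock genes left out, the time effects of both arms correlated at r = 0.262 across genes, and 7 of 100 relabellings gave a correlation as large (highest other 0.527), so this could not be decided.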
